A study of Homo sapiens with 4 samples.

How the data were processed

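The data came from a pooled CRISPR knockout screen in cells labelled THP1, a monocytic leukaemia cell line with a KMT2A-MLLT3 fusion. The cells carried the TKOv3 guide library in a lentiviral vector that also encodes Cas9, and guide sequences were amplified from genomic DNA and sequenced, per the labels' protocols. A guide whose target gene is needed for growth or survival becomes rarer in the population, and a guide whose target gene limits growth or survival becomes more common. The 4 libraries formed 2 groups of 2 replicates, taken from the labels: untreated cells at day 0, and cells kept in venetoclax, an inhibitor of the survival protein BCL2, for 18 days and 6 passages. Nothing in the labels says whether replicates came from separate cultures, so guide p-values measure only the spread between these samples, which may be technical. Gene p-values compare the ranks of a gene's guides with those of random guides, and other permutation p-values shuffle guides or genes. No p-value here is known to measure the spread between separate cultures. An untreated arm at day 18 was not analysed here, so the effect of the drug cannot be told apart from that of 18 days in culture.

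The deposited table gives RPM, reads scaled to a library total, for 71090 guides in each library, a unit read from the values. The submitters' processing notes name MAGeCK with no version or role, and the aligner, read counter and normalization step are not given in the sources used here. All values of a library were whole multiples of the RPM of 1 read, which ranged from 0.0614 to 0.0739 RPM, so 100% of values came out as whole reads at a tolerance of 0.01 of a read. The recovered reads summed over guides to 14005504 and 14516465 in the day 0 libraries and to 13175231 and 11891029 in the venetoclax libraries. The design fixed before the data were examined had assumed counts and named edgeR's quasi-likelihood test. Because the values are RPM, a log-scale test took its place, and the edgeR test on the recovered reads was added as an alternative after the unit was known. That count test called 391 genes depleted and 12 enriched.

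The guides comprised 142 controls against EGFP, LacZ and luciferase, which have no exact site in the human genome, and 70948 guides against 18053 genes. Each guide sequence of 20 bases was searched with its adjacent NGG motif in GRCh37, and sites were annotated with GENCODE v44 lifted to that build. Every gene guide had an exact site, 97.2% had a single site, and 98.0% cut a coding sequence. The deposited table held 26 gene names turned into dates, 2 of them with 8 guides, and 105 of the 109 guides under these names were given their gene back from the genomic site.

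Guides with a mean of at least 30 reads over the day 0 libraries were kept, which left 70139 guides and removed 951. Values were scaled by TMM (edgeR 4.0.16) and tested per guide on log2(RPM + 0.125), where 0.125 RPM is about 2 reads, with limma 3.58.1 and a mean-variance trend in R 4.3.3. Fold changes are on that scale, which understates the change of rare guides. Guide p-values, signed by direction, were ranked and combined per gene by robust rank aggregation with an alpha of 0.25, a rebuilt form of the rule that MAGeCK uses. A one-sided permutation p came from 1000000 random draws of as many guides, with Benjamini-Hochberg adjustment over the 17816 genes with at least 2 guides and a threshold of 0.05. A gene's log2 fold change is the mean over its guides, and its SD is over guides.

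Shifts of 26 gene lists fixed before the data were examined were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01 on gene-level means, with fry beside it. Named genes followed a rule also fixed then. It took the 12 genes with the largest change per direction among called genes with at least 3 guides, all changed the same way in both venetoclax libraries, then 23 apoptosis and leukaemia genes whatever their values, and up to 4 members of each list with the smallest p in the list's direction. Some genes under this rule and 1 of the lists are not reported here, for reasons other than their values. Genes outside this rule are named as chosen after their values were seen. The alternatives covered 4 other scalings, 2 other guide filters, 2 other pseudocounts, DESeq2 1.42.0, each library left out, a replicate block, and 3 other gene tests. Those added after seeing the data were the edgeR test, guides with 1 site only, subtraction of the median of the 50 nearest genes, and removal of part of chromosome 22.

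The procedure was tested on simulated reads for the day 18 against day 0 comparison, over 17816 genes with 200 changed. It recovered 48 of 50 genes at a log2 change of −2, 13 of 50 at −1, 24 of 50 at 1 and 50 of 50 at 2. These are the largest changes a guide could have. Each guide of a changed gene was given a random part of the change, so the mean over its guides was smaller. Among 17616 unchanged genes it called 1 depleted and 1 enriched, and it called 0 of 26 lists. Reads were drawn independently for each guide, so the simulation cannot show how often lists are called falsely where genes vary together. Tests and figures used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.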

Results

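Guide abundance was measured in 4 libraries of cells labelled THP1, with 2 replicates of untreated cells at day 0 and 2 of cells kept in venetoclax for 18 days. The day 0 libraries held 14005504 and 14516465 guide reads and the venetoclax libraries 13175231 and 11891029. A guide had a median of 189 and 196 reads at day 0 and of 171 and 156 reads at day 18. Guides with under 30 reads made up 3.10% and 3.04% of the library at day 18, against 1.55% and 1.40% at day 0. Replicates were not copies of each other, since the chi-square per degree of freedom was 7.68 between the day 0 libraries and 14.7 between the venetoclax libraries.

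The comparison of day 18 in venetoclax with day 0 asks which gene losses cells tolerated poorly or well over treatment and culture together. Guides against 395 of 17816 genes fell and guides against 16 genes rose, each in the same direction in both venetoclax libraries. HSPA5, an endoplasmic reticulum chaperone, fell most, with a log2 fold change of −4.22 ± 0.36 (SD, n = 4 guides). BAX, the effector that permeabilises the mitochondrial outer membrane, rose most, by 1.57 ± 0.12 (SD, n = 4 guides), a 2.98-fold gain. The median log2 fold change was −1.50 over depleted genes, which ranged from −4.22 to −0.64, and 0.91 over enriched genes, which ranged from 0.69 to 1.57. At an unadjusted p under 0.05, 1493 genes leaned toward depletion and 1113 toward enrichment. If no gene had changed, a share of about 0.05 of the 17816 genes would lean each way at that threshold. Leaving out venetoclax replicate 2 lowered the calls to 213 depleted genes, 190 of them among the 395, and 2 enriched genes, BAX and YBEY. Without venetoclax replicate 1, 261 and 6 genes were called, without day 0 replicate 1, 238 and 11, and without day 0 replicate 2, 271 and 9.

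**Figure D1:**
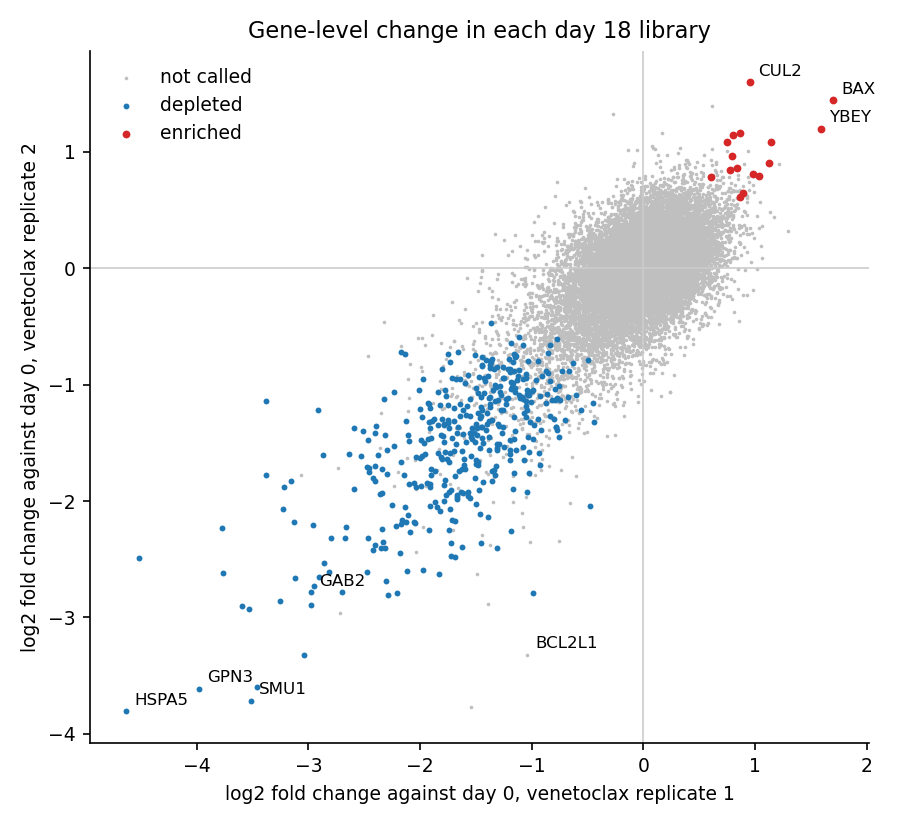
Each point is a gene, with its mean log2 fold change over guides against the day 0 mean in venetoclax replicate 1 (x axis) and in venetoclax replicate 2 (y axis), and colours mark the 395 depleted and 16 enriched genes. All called genes lie in the lower left or upper right quadrant, while BCL2L1, not called, was at −1.05 in replicate 1 and −3.32 in replicate 2. Genes of the Y chromosome are left out of the plot.

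After HSPA5, the largest decreases were in GPN3 (−3.80), SMU1 (−3.62), MED30 (−3.53), TMED2 (−3.50), POLR2L (−3.25), RNGTT (−3.23), TUBB (−3.20), SF3B3 (−3.18), PSMA6 (−3.06) and LRR1 (−2.94), and in RANGAP1, at −3.78 and −2.23 in the venetoclax replicates. Among these, POLR2L is a subunit of RNA polymerase II, RNGTT caps messenger RNA, TUBB is a beta tubulin and TMED2 works in vesicle transport. SF3B3 belongs to the spliceosome and PSMA6 to the proteasome. All guides of these 12 genes had log2 fold changes below 0, each gene fell in both venetoclax libraries, and the adjusted permutation p lay between 0.000636 and 0.0177. Guides against MED30 and RNGTT differed most among themselves, with SDs of 2.97 over 3 guides and 2.58 over 4.

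Lists of core essential genes shifted down. The spliceosome had a mean log2 fold change of −1.53 ± 0.66 (SD over 35 genes), the proteasome −1.45 ± 0.70 over 31, the CCT chaperonin −1.75 ± 0.70 over 8 and DNA replication −1.09 ± 0.61 over 40. Cytosolic tRNA synthetases had a mean of −0.87 ± 0.45 over 20 genes, and the cytosolic ribosome one of −0.80 ± 0.46 over 53. In that order 13, 13, 6, 12, 5 and 4 genes passed the threshold over all genes, and 28, 26, 8, 28, 13 and 30 did when adjusted over the list alone. Examples were SF3B4 at −2.49 and PRPF4 at −1.27, PSMB7 at −2.70, CCT6A at −2.84 and CCT3 at −2.16, PCNA at −2.55 and POLA2 at −1.54, KARS at −1.59, and RPL3 at −1.40. The camera adjusted p was 8.81e-31 for the spliceosome and 4.66e-13 for the tRNA synthetases. With an estimated correlation no list of the 26 kept its call, and for these 6 lists the adjusted p was 0.0943, or 0.170 for the ribosome, in a design with 2 libraries per group. The estimate was 0.126 for the ribosome, 0.0953 for the proteasome and 0.0510 for the spliceosome. It was below the preset 0.01 for tRNA synthetases (−0.0446), the CCT chaperonin (−0.0262) and DNA replication (−0.0012). A higher correlation therefore does not explain the lost calls of these last lists. Olfactory receptor genes, which these cells are not thought to need, had a mean of 0.02 ± 0.25 over 329 genes with 0 called (adjusted p = 0.181), and a mean of −0.30 when libraries were scaled on control guides. Those with the smallest p toward enrichment were OR52N2 at 0.54 and OR2T4 at 0.50. Gene log2 fold change separated the 187 core genes from these receptors with an area under the ROC curve of 0.961 (95% bootstrap interval 0.939 to 0.979).

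Within the apoptosis machinery the guides that rose were those against BAX and CASP9, the initiator caspase of the apoptosome. CASP9 rose by 0.97 ± 0.30 (SD, n = 4 guides), at an adjusted permutation p of 0.0134, against 0.00356 for BAX. APAF1 at 0.84 and PMAIP1, which encodes NOXA, at 0.76 did not pass over all genes, at adjusted permutation p of 0.164 and 0.111. The list of intrinsic apoptosis effectors had a mean of 0.23 ± 0.59 over 17 genes, with 2 enriched genes over all genes and 5 enriched and 1 depleted when adjusted over the list alone. It shifted up against other genes (camera adjusted p = 0.00825, adjusted p = 0.197 with an estimated correlation). Scaling on control guides moved the median of all genes to −0.31 and turned the list mean below 0, to −0.09, while the shift against other genes stayed past the threshold. CASP9 lost its call without day 0 replicate 1 (adjusted p = 0.0520) and without venetoclax replicate 2 (adjusted p = 0.406), while BAX kept its call under every alternative run.

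The 4 guides against BAX cut its coding exons 3, 4, 5 and 6 on chromosome 19, from position 49458954 to 49464839 of GRCh37, and their log2 fold changes were 1.45, 1.74, 1.55 and 1.56. Those against CASP9 cut coding exons 1, 2, 4 and 5 on chromosome 1, from 15832495 to 15850697.

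BCL2, the target of venetoclax, was at 0.00 ± 0.19 (SD, n = 4 guides), with guides in coding exons 2 and 3 on chromosome 18, from 60795864 to 60985505. BCL2L1, which encodes BCL-XL, was at −2.18 ± 1.82 and did not pass (adjusted permutation p = 0.0649), and it passed without venetoclax replicate 1 (adjusted p = 0.000713) and without day 0 replicate 1 (adjusted p = 0.0432). The BCL2L1 guide at −1.45 stood at 2.97 and 4.18 RPM at day 0, and at 13.4 and 0 RPM in venetoclax replicates 1 and 2. The other guides against BCL2L1 were lower in both venetoclax libraries than at day 0. MCL1 was at −0.88 ± 0.74, BCL2A1 at 0.05, BCL2L2 at 0.07, BAK1 at 0.24 and BCL2L11, which encodes BIM, at −0.04, and none of these passed. All 4 guides against BAK1 have 2 or 3 exact genomic sites. Over all gene guides, those with 2 sites had a median of −0.23, against 0.01 with 1 site. The anti-apoptotic BCL2 family list had a mean of −0.59 ± 0.98 over 5 genes and a median of 0.00, with 0 genes called and 1 depleted when adjusted over the list alone (camera adjusted p = 0.181), but it passed without day 0 replicate 2 (adjusted p = 0.0368) and without venetoclax replicate 1 (adjusted p = 0.0170). BID was at −0.90 ± 0.71 (adjusted permutation p = 0.0649) and lies in the part of chromosome 22 described further on. The extrinsic apoptosis list, with a mean of −0.18 over 10 genes, held CASP10 at −0.53, FADD at −0.39 and TNFRSF10B at −0.07 and did not shift (camera adjusted p = 0.309). In the list of MCL1 and NOXA turnover 2 of 9 genes fell, the ubiquitin ligase HUWE1 to −0.92 and the conjugating enzyme UBE2J2 to −1.02. MARCHF5 at −0.21 and FBXW7 at 0.12 did not pass. The mean of this list was −0.12 and its median 0.12, without a shift (camera adjusted p = 0.707).

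**Figure D2:**
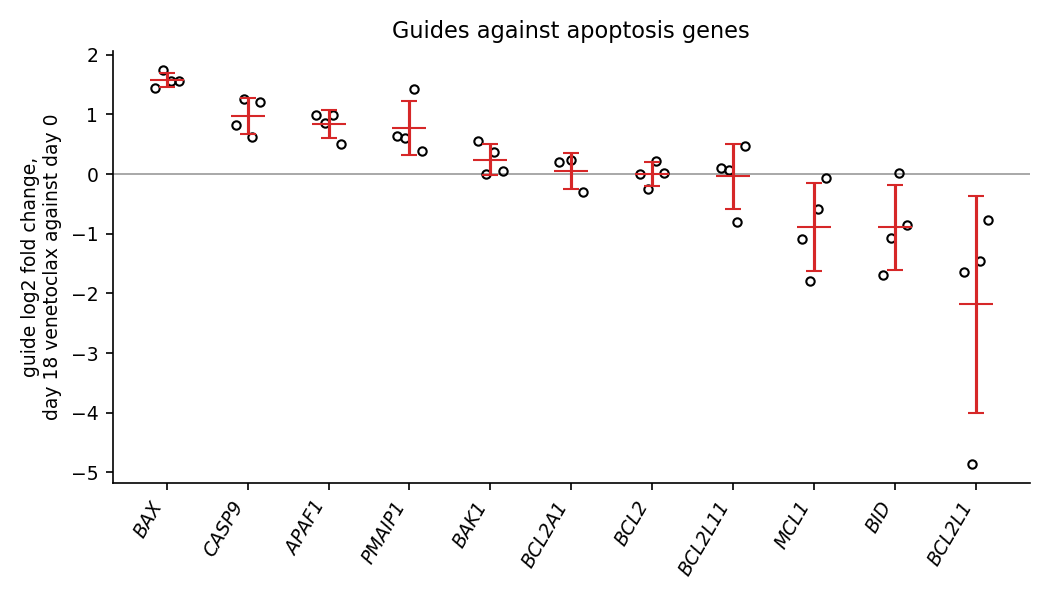
Open circles are single guides, red lines their mean and bars the SD over 3 or 4 guides, for some of the apoptosis genes named before the data were examined, and the y axis is the log2 fold change of day 18 in venetoclax against day 0. Guides against BAX lie between 1.45 and 1.74, those against BCL2 between −0.25 and 0.22, and those against BCL2L1 between −4.86 and −0.78.

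Several enriched genes act in the mitochondrion. They included YBEY at 1.39 ± 0.52, NOA1 at 1.11 ± 0.31, FTSJ2 at 1.01 ± 0.36, MRPS17 at 1.01 ± 0.54, WARS2 at 0.90 ± 0.23, RBFA at 0.88 ± 0.60 and C6orf203 at 0.85 ± 0.54 (SD, n = 4 guides each). YBEY, FTSJ2 and RBFA act on mitochondrial ribosomal RNA or ribosome assembly, and WARS2 is the mitochondrial tryptophanyl-tRNA synthetase. YBEY kept its call under every alternative run, whereas the others lost theirs without venetoclax replicate 2, at adjusted p of 0.0653 for NOA1, 0.346 for FTSJ2, 0.0831 for MRPS17, 0.363 for WARS2, 0.147 for RBFA and 0.421 for C6orf203. Some of these other genes also lost their call when venetoclax replicate 1 or day 0 replicate 2 was left out. Subtracting the median of the 50 nearest genes also ended the calls of FTSJ2 (adjusted p = 0.188), WARS2 (0.400) and RBFA (0.144). The medians subtracted were 0.23, 0.28 and 0.15, smaller than the changes of these genes. The mitochondrial ribosome list had a mean of 0.17 ± 0.32 over 74 genes, of which MRPS17 and MRPS6 (0.69, adjusted p = 0.612 without venetoclax replicate 2) rose, or 4 genes when adjusted over the list alone, and MRPL1 at 0.72 and MRPS25 at 0.42 did not pass. It shifted up (camera adjusted p = 6.57e-05, adjusted p = 0.195 with an estimated correlation), with a mean of −0.15 under scaling on control guides. Complexes III and IV and ATP synthase shifted down, with a mean of −0.28 ± 0.46 over 34 genes (camera adjusted p = 0.00102, adjusted p = 0.179 with an estimated correlation). In that list COX5B (−1.11) and COX10 (−0.96) fell, UQCRFS1 at −0.78 and ATP5H at −0.85 did not pass, and COX4I1, named after its value was seen, rose by 0.91 ± 0.87. Adjusted over the list alone, 4 of its genes fell and 1 rose. Complex I, with a mean of −0.10 ± 0.28 over 43 genes, did not shift (camera adjusted p = 0.408), and its lowest p belonged to NDUFA11 at −0.48. The mitochondrial ribosome mean exceeded that of complexes III and IV and ATP synthase by 0.45 and that of complex I by 0.27, each at an adjusted two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Genes were permuted there and are not independent replicates.

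The mitochondrial dynamics and cristae list shifted down, with a mean of −0.43 ± 0.70 over 20 genes (camera adjusted p = 0.00355, adjusted p = 0.195 with an estimated correlation). Its depleted genes were both of mitochondrial fission, the GTPase DNM1L at −2.54 ± 0.53 and its receptor FIS1 at −0.88 ± 0.40. DNM1L kept its call under every alternative run, and FIS1 lost its call when any of the 4 libraries was left out, at adjusted p from 0.0575 to 1. Adjusted over the list alone, 4 genes were depleted and 1 was enriched. The prohibitins PHB2 at −1.66 and PHB at −0.55 did not pass.

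The remaining enriched genes under the naming rule were CUL2 at 1.27 ± 0.19 and VHL at 0.91 ± 0.33, a scaffold and the substrate receptor of a ubiquitin ligase that marks hypoxia-inducible factors for degradation, and LMO4, a LIM-domain transcription cofactor, at 0.81 ± 0.46. The 4 CUL2 guides were at 1.25, 1.09, 1.21 and 1.54, and the gene lost its call without venetoclax replicate 2 (adjusted p = 0.147). VHL and LMO4 lost theirs when any of the 4 libraries was left out, at adjusted p up to 0.346 and 0.450. MTG1 at 0.74 and ADAM30 at 0.77, named after their values were seen, complete the 16.

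**Figure D3:**
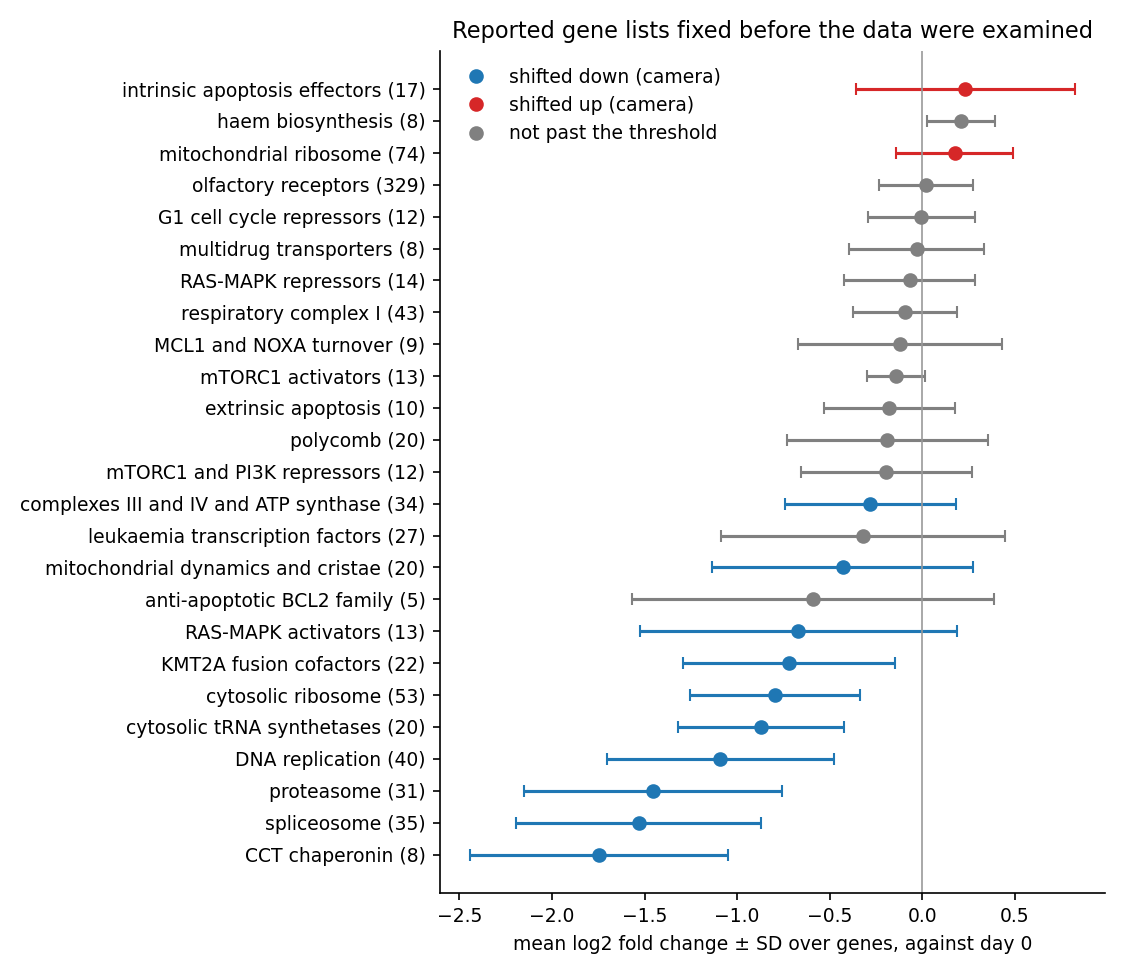
Points are mean gene log2 fold changes of the fixed lists reported here, day 18 in venetoclax against day 0, bars are the SD over genes, and the number of genes tested stands in parentheses on the y axis. The CCT chaperonin has a mean of −1.75 and intrinsic apoptosis effectors one of 0.23, with colour for lists past the camera threshold at the preset correlation.

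Cofactors of KMT2A fusions shifted down, with a mean of −0.72 ± 0.57 over 22 genes (camera adjusted p = 2.6e-10, adjusted p = 0.0943 with an estimated correlation). Of these, 4 were depleted over all genes and 12 over the list alone. The polymerase-associated factors CDC73 (−2.01) and CTR9 (−1.16), KMT2A (−1.72) and the menin gene MEN1 (−1.34) fell. KMT2A and MEN1 lost their calls in the count test (adjusted p = 0.0578 and 0.0532). The methyltransferase DOT1L was at −1.42 (adjusted permutation p = 0.0857), and MLLT3, the fusion partner of KMT2A in THP1, at 0.06 ± 0.24 (SD, n = 4 guides). Leukaemia transcription factors as a list had a mean of −0.32 ± 0.76 over 27 genes and did not shift (camera adjusted p = 0.147), but did without day 0 replicate 2 (0.0225) and without venetoclax replicate 1 (0.0101). In it STAT5B (−2.23), MYC (−2.09), MYB (−1.23) and RUNX1 (−1.08) fell, and adjusted over the list alone 7 genes were depleted and 1 was enriched. SPI1, which encodes the myeloid factor PU.1, was at 0.42 ± 0.28 and did not pass (adjusted permutation p = 0.836). In the polycomb list EED (−1.40) and SUZ12 (−1.33) fell, RBBP4 at −0.93 and PHC1 at −0.44 did not pass, 3 of 20 genes were depleted over the list alone, and the mean of −0.19 did not shift (camera adjusted p = 0.309).

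Among growth signalling genes, activators of RAS and MAPK shifted down, with a mean of −0.67 ± 0.86 over 13 genes (camera adjusted p = 0.000119, adjusted p = 0.376 with an estimated correlation). The adaptor GAB2 (−2.88), the exchange factor SOS1 (−1.72) and the adaptor GRB2 (−1.05 and −0.94 in the venetoclax replicates) fell, and adjusted over the list alone 5 genes were depleted and 1 was enriched. GRB2 lost its call after the median of its 50 nearest genes was subtracted (adjusted p = 0.0760). NRAS was at 0.38 ± 0.08 and did not pass (adjusted permutation p = 0.421). Repressors of RAS and MAPK had a mean of −0.07 over 14 genes, against an upward camera direction (adjusted p = 0.940), with SPRED1 at 0.42 and 0 called. Activators of mTORC1 had a mean of −0.14 over 13 genes with 0 called (camera adjusted p = 0.294). Repressors of mTORC1 and PI3K had a mean of −0.19 over 12 genes without a shift (camera adjusted p = 0.309). Of these TSC2 fell by 1.28, while TSC1 at −0.72 did not pass. G1 repressors had a median of 0.06 and a mean of −0.00 over 12 genes (camera adjusted p = 0.707), with CDKN2C at 0.30 and 0 called. Haem biosynthesis had a mean of 0.21 over 8 genes with 0 called (camera adjusted p = 0.0582), with PPOX at 0.50. It passed without day 0 replicate 2 (adjusted p = 0.0347) and without venetoclax replicate 2 (adjusted p = 0.0271), and its mean was −0.11 under scaling on control guides. Multidrug transporters had a mean of −0.03 over 8 genes against an upward camera direction (adjusted p = 0.917), with ABCG2 at 0.51 and ABCB1 at 0.08 and 0 called.

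Depletion also followed position along chromosome 22. All 74 tested genes from position 17072240 to 23610697 of GRCh37, from CCT8L2 to BCR, had log2 fold changes below 0, with a median of −0.88 and an SD of 0.45. In this stretch 21 genes fell, which is 5.32% of all depleted genes. The 324 tested genes beyond BCR on the same chromosome had a median of −0.10, and 14 of them fell. This stretch was chosen after the values were seen.

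**Figure D4:**
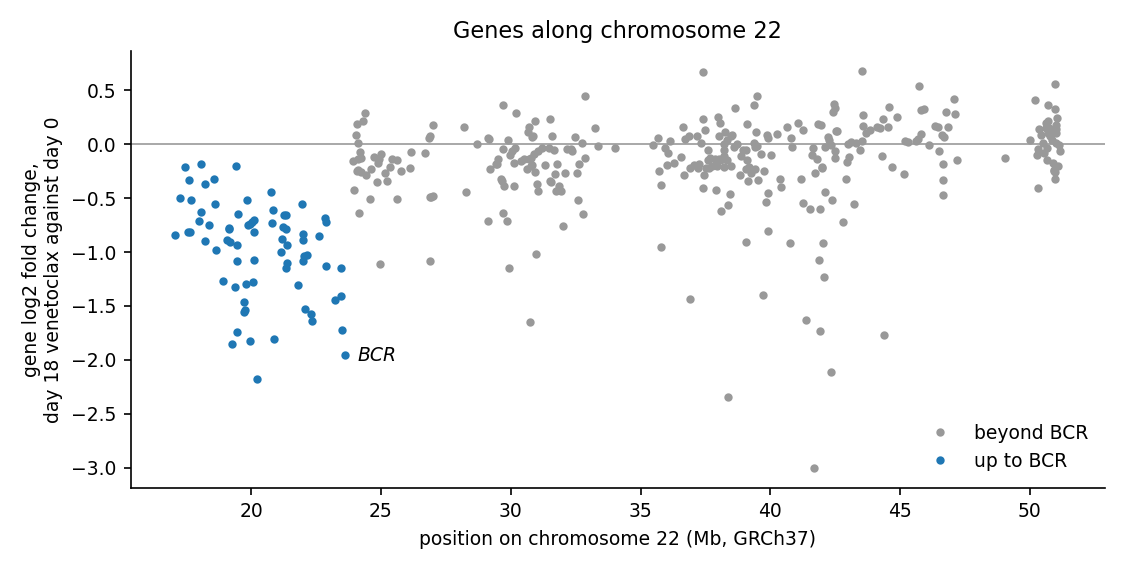
Points are genes at their position on chromosome 22 in Mb of GRCh37 (x axis) with their log2 fold change of day 18 in venetoclax against day 0 (y axis), coloured for the stretch up to BCR. The 74 genes up to BCR have a median of −0.88, and the 324 beyond it a median of −0.10.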

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

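The test on sites in the human genome was chosen only after its result was seen, and the tests on GC content and day 0 abundance were not. For these and for the tests with a 95% bootstrap interval under other observations, an explanation was taken as met where the whole interval lay within what it predicts, and as excluded where the whole interval lay outside that and the value met the opposing bound, a reading settled after the values had been seen.

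Control guides against EGFP, LacZ and luciferase entered no gene comparison, yet they stood above their day 0 level in the venetoclax libraries, with a median log2 fold change of 0.304 over 133 guides, 98 of them above 0. Their excess over olfactory receptor guides with 1 genomic site was 0.27 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Among olfactory receptor guides, the 45 with 2 or more sites lay below those with 1 site by a median difference of −0.214 (two-sided permutation p = 0.00834), which is consistent with a cost of cutting DNA that guides without a site do not pay. Set against olfactory receptor guides of equal GC count, control guides still differed by 0.311 (95% interval 0.192 to 0.393), and against those in the same bin of day 0 reads by 0.219 (0.122 to 0.317). Both intervals exclude a difference under 0.1, which argues against either as the whole cause, but they reach below the 0.2 set beforehand, so a part played by either stays open, and no biological explanation other than the cost of cutting was tested.

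Of 333 guides with 0 reads in both day 0 libraries, 31 had more than the 3 reads that a count of 0 allows in a venetoclax library, a signal in guides that the comparison left out except where no guide filter was applied, and 8 had reads in both venetoclax libraries.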

How the results depend on the processing

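Alternatives added after seeing the data were the edgeR test on recovered reads, guides with 1 site, subtraction of the regional median and removal of chromosome 22 up to BCR. Over 2810 repeats of 128 named genes, 2607 kept their side of the threshold, 176 lost a call, 27 gained a call and 0 reversed. The 2607 include genes not called in either run. They also include 128 from the setting with the median over guides, which left the gene calls of the main run untouched and could not differ. Without chromosome 22 up to BCR, 386 genes were depleted, 374 of them among the 395, and 16 enriched. With the regional median subtracted, 401 were depleted, 331 of them shared, and 14 enriched, 9 of them shared, and leukaemia transcription factors passed (adjusted p = 0.0179). The edgeR test gave 391 and 12 genes, and DESeq2 380 and 16. Guides past the threshold numbered 591 and became 2351 under scaling on control guides and 1319 with DESeq2. Reads summed per gene gave 866 depleted and 239 enriched genes, and ranking guides by log2 fold change gave 4 enriched genes. The area under the ROC curve was 0.944 with the median over guides. With an estimated correlation, adjusted p was 0.170 for the cytosolic ribosome, 0.0943 for proteasome, spliceosome, tRNA synthetases, DNA replication, CCT chaperonin and KMT2A cofactors, 0.195 for mitochondrial ribosome and mitochondrial dynamics, 0.179 for complexes III and IV and ATP synthase, 0.197 for intrinsic apoptosis, and 0.376 for RAS-MAPK activators. The estimate was above the preset 0.01 for mitochondrial ribosome (0.0227) and RAS-MAPK activators (0.322). It was below 0.01 for KMT2A cofactors (−0.0192), mitochondrial dynamics (−0.0217), complexes III and IV and ATP synthase (−0.0302) and intrinsic apoptosis (−0.0096). Where it was below, a higher correlation does not explain the lost call. Leaving out each library gave 7 to 7142 guides (7 without day 0 replicate 1, 21 without day 0 replicate 2, 4479 and 7142 without venetoclax replicates 1 and 2), 213 to 271 depleted genes, 2 to 11 enriched genes and an area of 0.940 to 0.957, and adjusted p of 0.0170 to 0.346 for the anti-apoptotic BCL2 family, 0.0101 to 0.544 for leukaemia transcription factors and 0.0271 to 0.284 for haem biosynthesis, where the lone library left in a group is assumed to vary like the other group. Replicate differences at day 0 and in venetoclax had a correlation of 0.0145 over guides. This shows no pairing by replicate number but cannot exclude it. The replicate block gave 1680 guides past the threshold, 391 depleted and 20 enriched genes. The cause of these differences was not tested. Leaving out day 0 replicates 1 and 2 and venetoclax replicates 1 and 2 ended 24, 24, 23 and 32 calls of named genes. Below a mean of 30 reads at day 0 a guide was not tested. A simulated log2 change of −1, of which each guide had only a part, was recovered for 26% of genes.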

Other observations

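The gene groups here were listed, and the tests on copy number and on a minority of cells were chosen, only after the values were seen, while the tests on GC content, abundance, 9q34 and mitochondrial genes were written before their results. Guides against the SAGA coactivator complex had a mean log2 fold change of −0.69 ± 0.55 over 15 genes, and TADA1 (−1.93), TADA2B (−1.68), SUPT20H (−1.10) and KAT2A (−0.90) fell (camera adjusted p = 4.31e-07, adjusted p = 0.288 with an estimated correlation). The RNA m6A writer had a mean of −0.81 ± 0.75 over 8 genes, of which METTL3 (−2.15) and KIAA1429 (−1.62) fell (camera adjusted p = 2.44e-05, adjusted p = 0.288 with an estimated correlation). Of 6 mitochondrial fission genes 4 fell, DNM1L, FIS1, MIEF1 (−0.81) and the ubiquitin ligase MUL1 (−2.55) (camera adjusted p = 3.09e-05, adjusted p = 0.348 with an estimated correlation). In the cullin 2 and VHL ligase group CUL2 and VHL rose while RBX1 (−1.63) and UBA3 (−1.33) fell, and the group did not shift (camera adjusted p = 0.225).

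Genes of BCR-ABL1 signalling were depleted in cells labelled THP1, a line not known to carry that fusion. ABL1 (−2.58 ± 1.35) and BCR (−1.95 ± 1.98, SD, n = 4 guides each) fell, although 1 BCR guide lay above 0. ABL1 was at −3.38 and −1.77 in the venetoclax replicates. With GAB2, SOS1, STAT5B and GRB2, 6 of 11 such genes fell (mean −1.25, camera adjusted p = 9e-08, adjusted p = 0.264 with an estimated correlation). Of 8 erythroid transcription factors LDB1 (−1.94) and NFE2 (−1.17) fell (camera adjusted p = 0.000172, adjusted p = 0.278 with an estimated correlation). GATA1 (−2.65), LMO2 (−1.44), GFI1B (−0.71), TAL1 (−0.01), KLF1 (−0.10) and ZFPM1 (0.19) did not pass. Among 14 genes listed as monocytic leukaemia dependencies 0 were called (mean 0.15, camera adjusted p = 0.0604). That list leaves out KMT2A (−1.72), MEN1 (−1.34) and MYB (−1.23), which fell. KMT2A fusion cofactors shifted down, with 4 of 22 genes called (camera adjusted p = 2.6e-10, adjusted p = 0.0943 with an estimated correlation). A hypothesis is that the sequenced cells were, or were replaced by, a line that carries BCR-ABL1 such as K562, in which 9q34 from ABL1 to NUP214 is amplified with BCR. In a test written before those neighbours were seen, the 20 guides of that segment other than those against ABL1 had a median of −1.097 (95% interval −1.68 to −0.79), against −0.09 over 91 genes within 3 Mb on either side. GAB2, SOS1, GRB2 and STAT5B had a median difference from the 50 nearest genes of −1.717 (−2.65 to −0.79). That lies beyond the 0.5 that local copy number alone allows. The genes were picked because they had been called depleted, so a low value was likely beforehand. The interval only runs from the lowest to the highest of their values, so this does not decide on local copy number. Local copy number also stays open for BCR and ABL1, whose guides differed from the others of their own segments by a median of −1.25 (−2.90 to −0.15). A minority of such cells at a constant share of a THP1 culture would keep genes above about −1. The 20 guides of ABL1, GAB2, SOS1, GRB2 and STAT5B had a median of −1.795 (−2.49 to −1.37). These genes too were picked because they had been called, and the median over all 11 listed genes was −0.996. The test therefore cannot decide on such a minority. A minority that outgrew the other cells was not tested, and no genotype of these cells was analysed here.

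All 74 genes from the start of chromosome 22 up to BCR lay below their day 0 level together, and 21 of them fell. A loess on guide GC content left the median at −0.8426 (95% interval −0.95 to −0.80), and the difference from guides of other regions in the same bin of day 0 reads was −0.8658 (−0.96 to −0.79), so neither accounts for it. Extra DNA copies, each a further cut, may explain it, and 69 genes outside every fixed list had a median of −0.8778, but the stretch was found from these same genes, so this cannot be told apart from other local causes. Over all gene guides the median was 0.01 with 1 genomic site, −0.23 with 2 and −0.45 with 3 or more.

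A hypothesis was that loss of mitochondrial protein synthesis as a class favoured cells in this arm. Its prediction that mitochondrial tRNA synthetases other than WARS2 would shift up was not met. They had a mean of −0.09 ± 0.42 over 16 genes (camera adjusted p = 0.5911). That list leaves out WARS2, which was called, and the mitochondrial ribosome list shifted up (camera adjusted p = 6.57e-05). The result therefore holds for these synthetases and does not decide on the class. The mean of the mitochondrial ribosome list stayed at 0.223 after the median of the 50 nearest genes was subtracted, above the 0.1 set beforehand. Mitochondrial translation factors (mean 0.04 over 13 genes, camera adjusted p = 0.225) and mitochondrial DNA upkeep genes (mean 0.18 over 11 genes, camera adjusted p = 0.0604) did not shift.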
